A study of Mus musculus with 3 samples.

How the data were processed

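The study measured RNA of cells recovered by bronchoalveolar lavage, called lung macrophages in the series title, on 2-colour spotted arrays. There were 3 arrays, 1 each for mice given saline, crystalline silica or titanium dioxide (TiO2). Per the labels, each lavage RNA was extracted on spin columns, amplified with the RiboAmp kit, copied to cDNA and hybridised against a commercial pool of mouse reference RNA (Universal Mouse Reference RNA), whose cDNA carried Alexa Fluor 532. The number of mice behind each lavage RNA and the dye of the lavage cDNA are not given in the sources used here. The samples were grouped by their titles.

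The authors deposited 1 value per spot and array, which was read as a log2 ratio of the 2 channels. The base was inferred from the values: the highest deposited value lay just below 16 on each array, the log2 range of a 16-bit scanner, whereas the natural log of the same range ends at 11.1. The scanner, background correction, spot filter, normalization and centring are not given in the sources used here. The numerator of the ratio is also not given, and the direction of the ratio therefore stays unknown. "Above" and "below" refer to the deposited ratio throughout, not to the amount of RNA in the lavage cells. All pairs of arrays correlated above 0, so the 3 arrays were read as running the same way. The column medians of the deposited log2 ratios were 0.16 on the saline array, 0.13 on the silica array and 0.12 on the TiO2 array.

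The table had 5862 spots that belonged to 975 sequence accessions. Of these accessions, 973 had 6 spots and 2 had 12 spots. On each array the values of all 977 sets of 6 spots were listed in ascending order with blanks last. The same row of different arrays is therefore not the same physical spot, and spots were not paired between arrays. Spots of an accession were averaged on each array, and the SD over its measured spots is given as the error. That SD covers printing, hybridisation and scanning within 1 array, not variation between mice or arrays.

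Accessions were matched without version to every identifier and synonym of a RefSeq gene table for mouse assembly GRCm38.p6. A total of 16 accessions (1.64%) matched, all as a listed synonym of 1 gene, and 959 did not match and are left unnamed. The result of 1 matched gene is not reported here. The array files name no genome build, and no coordinates are given. The 37 gene lists fixed before the data were examined (cell type markers, pathways, and 2 lists meant to settle the direction of the ratio) held 0 of the 16 matched genes. The planned list medians, the percentiles among random lists and the check of the ratio's direction were therefore not computed.

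The mean of each accession was centred on the array's median over the 662 accessions with a value on all 3 arrays. The subtracted medians were 0.27 (saline), 0.086 (silica) and 0.044 (TiO2) on the log2 scale. A comparison is the difference of 2 centred log2 ratios. The common reference cancels in it only if both arrays respond on the same scale. The median absolute deviation of the centred ratios was 0.72 on saline, 0.24 on silica and 0.25 on TiO2. Full cancellation is therefore not assured in the 2 saline comparisons. With 1 array per group there is no replicate check and no test, and no p-value was computed. Accessions were counted as 2-fold apart at an absolute difference of at least 1. For accessions with every spot measured on both arrays, the number whose 2 sets of spots did not overlap is given. For 6 spots against 6, a random arrangement gives no overlap in 0.216% of cases. That figure takes the spots of both arrays as interchangeable. An offset or scale difference between 2 arrays also separates spots, so it is no chance level for these comparisons. The error of a difference combines the SDs of the spots of both arrays (SE). The precision is limited by the number of arrays.

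The rule for named genes, fixed before the data were examined, named the 12 highest and 12 lowest differences among 2-fold accessions with a gene symbol, and only 2 of the matched accessions reached that size in any comparison. The other matched genes are given as values and were chosen after their values were seen. So few names were available that unmatched accessions are printed by identifier, 2 in each direction and comparison, from the accessions with every spot measured on all 3 arrays. That restriction was also chosen after the values were seen.

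Alternatives were deposited values without centring, quantile normalization, a lowess trend (span 0.4) of the difference on the mean ratio, a common scale (median absolute deviation) for the arrays, the median of spots, accessions measured on the 2 arrays compared, thresholds of 1.5-fold and 3-fold, and leaving out accessions with an absolute centred log2 ratio above 5. The common scale was the mean of the 3 median absolute deviations, so it widened the silica and TiO2 arrays and narrowed the saline array. Counting each spot on its own was planned and not run because spots cannot be paired. Added after seeing the data were accessions with every spot measured on all 3 arrays, leaving out spots at the top value of the array, and leaving out the saline array. The counting was tested on simulated data with 200 of 662 accessions shifted by 1.5 on the log2 scale and noise drawn from the spots. It recovered 93.0% of shifted accessions for silica minus saline, 97.0% for TiO2 minus saline and 99.5% for silica minus TiO2. It also counted 19, 18 and 0 of the 462 unshifted accessions. Both simulated arrays were drawn from the means and spot SDs of 1 array, saline for the first 2 comparisons and TiO2 for the third. They therefore share 1 scale and carry no variation between arrays, and these counts are not an error rate for the real comparisons. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.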

Results

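RNA of lavage cells from mice exposed to mineral particles was compared with that of saline-instilled mice on 2-colour arrays. Mice received 30 µl intranasally at 6 weeks of age and were lavaged at 14 weeks, 8 weeks later. The saline, silica and TiO2 groups had 1 array each. The silica dose was 1 mg per mouse and the TiO2 dose was 500 µg, so the particles were not compared at a matched dose. Crystalline silica is a mineral dust that causes lung fibrosis, and TiO2 is often used as a comparison dust of low toxicity. The values are log2 ratios between lavage RNA and a common pool of mouse reference RNA, and it is not known which of the 2 is the numerator.

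The arrays differed in how much was measured. Of 5862 spots, the silica array had a value for 5141 (87.7%, 95% Wilson interval 86.8 to 88.5), the TiO2 array for 4792 (81.7%, 80.7 to 82.7) and the saline array for 3714 (63.4%, 62.1 to 64.6). These intervals cover counting error over spots only and treat spots as independent. Spots of an accession were mostly measured or blank together, so the intervals are too narrow. On the saline array, every spot was measured for 567 accessions and no spot for 313. At least 1 spot was measured for 887, 842 and 662 of the 975 accessions on the silica, TiO2 and saline arrays. All 662 accessions measured on the saline array also had a value on both other arrays, and 80 were blank on all 3. The median SD over replicate spots was 0.082 on the silica array, 0.071 on the TiO2 array and 0.095 on the saline array (log2 units). The 90th percentile of that SD was 0.41, 0.49 and 0.89. The spread of centred ratios over the 662 accessions, as the median absolute deviation, was 0.24 for silica, 0.25 for TiO2 and 0.72 for saline.

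The first comparison asks how lavage cells of silica-instilled mice differed from those of saline-instilled mice. Among genes with a name, *Cdkn1b*, which encodes the cell cycle inhibitor p27, and *Arhgap35*, which encodes a GTPase-activating protein, lay furthest apart. The centred ratio of *Cdkn1b* was -0.99 ± 0.017 (SD, n = 6 spots) on the saline array and -0.018 ± 0.044 (SD, n = 6 spots) on the silica array, a difference of 0.98 with an SE of 0.019 over spots, just under 2-fold. That of *Arhgap35* was 1.87 ± 1.10 (SD, n = 5 spots) on the saline array and 0.58 ± 0.20 (SD, n = 6 spots) on the silica array, a difference of -1.29 with an SE of 0.50. The sign of the *Arhgap35* difference turned under quantile normalization (0.54) and after removal of the trend with the ratio (0.61). *Alox5*, which encodes the 5-lipoxygenase of leukotriene synthesis, differed by -0.19 (SE 0.050), and *Mbnl2*, which encodes a splicing regulator, by -0.35 (SE 0.031). The values of the other genes moved with the scaling or centring, and the range over the alternatives is given with each. *Rab4a*, a GTPase of endosome recycling, differed by 0.37 (range 0.16 to 0.37) and *Rbpj*, the transcription factor of Notch signalling, by 0.28 (0.093 to 0.45). *Col16a1*, a collagen gene, differed by 0.28 (-0.20 to 0.28) and *S1pr1*, a receptor for sphingosine 1-phosphate, by 0.24 (-0.19 to 0.24), so that their signs turned. *Vezf1* differed by 0.23 (0.049 to 0.29), *F8a* by 0.18 (-0.0010 to 0.24) and *Prkag2*, a regulatory subunit of AMP-activated kinase, by 0.13 (-0.092 to 0.13). On one scale for all arrays, *Alox5* (-1.42) and *Mbnl2* (-2.06) passed 2-fold and *Cdkn1b* came to 0.52, while under quantile normalization *Cdkn1b* came to 1.05. The one scale widens the silica array and narrows the saline array, so larger values on it are not larger measured differences.

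Over all 662 accessions, 201 (30.4%) were at least 2-fold apart between silica and saline. The silica ratio was above the saline ratio in 18 of them and below it in 183. On the saline array 181 of the 662 lay at least 2-fold above the array's own median and 58 below it, against 22 and 64 on silica. The split thus follows the long upper tail of the saline array. If the deposited ratio has the lavage RNA as its denominator, these 2 numbers change places as statements about the lavage cells. After quantile normalization the split was 65 above and 85 below, and after removal of the trend with the ratio it was 37 and 53. In every comparison these 2 settings push the split toward balance by construction. Of 566 accessions with every spot measured on both arrays, 114 were 2-fold apart and the spots of 112 of these did not overlap. Non-overlap was common at any size, in 436 of the 566 (77.0%). The largest differences with every spot measured on all 3 arrays were accession AI838874 (2.31, SE 0.045) and AI852054 (1.72, SE 0.13) above saline, and AI847817 (-4.79, SE 2.13) and AI845477 (-4.77, SE 0.42) below it. The saline mean of AI847817 includes 1 spot at the top value of the array, and its difference was -2.68 without that spot. Of the 12 largest differences of any accession, 11 rested on fewer than 6 spots on an array, 3 on a single spot, and 5 included a spot at the top value of its array. These 3 arrays cannot show whether the difference exceeds the variation between mice.

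The second comparison sets TiO2 against saline. *Alox5* was the named gene furthest apart: its centred ratio was -2.51 ± 0.046 (SD, n = 6 spots) on the TiO2 array and -0.97 ± 0.081 (SD, n = 6 spots) on the saline array, a difference of -1.54 (SE 0.038), or 2.91-fold. It was -0.86 after removal of the trend with the ratio, under 2-fold, and -3.55 with all arrays on one scale, which widens the TiO2 array. *Arhgap35* differed by -1.20 (SE 0.49), and this sign turned under quantile normalization (0.44), after trend removal (0.54) and with all arrays on one scale (0.060). *Cdkn1b* differed by 0.98 (SE 0.0091), to a level on the TiO2 array of -0.0099 ± 0.015 (SD, n = 6 spots). *Mbnl2* differed by -0.59 (SE 0.023), and by -2.35 on one scale, -0.16 under quantile normalization and -0.0058 after trend removal. *Cdkn1b* came to 0.54 on one scale and 1.07 under quantile normalization. *S1pr1* differed by 0.41 (range over the alternatives 0.15 to 0.41), *Rbpj* by 0.29 (0.060 to 0.36) and *F8a* by 0.27 (0.046 to 0.38). The sign turned under at least 1 alternative for *Col16a1* (0.37, range -0.043 to 0.37), *Rab4a* (0.24, -0.033 to 0.24), *Vezf1* (0.18, -0.049 to 0.18) and *Prkag2* (0.011, -0.26 to 0.011).

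Of the 662 accessions, 205 (31.0%) were at least 2-fold apart between TiO2 and saline, 20 with the TiO2 ratio above and 185 with it below. The split was 62 above and 61 below after quantile normalization, and 50 and 36 after removal of the trend. Of 565 accessions with every spot measured on both arrays, 120 were 2-fold apart, and the spots of 117 of these did not overlap, against 453 (80.2%) of all 565. The largest differences with every spot measured on all 3 arrays were AI838874 (2.46, SE 0.042) and AI843756 (1.65, SE 0.018) above saline, and AI845477 (-4.34, SE 0.42) and AI854624 (-4.21, SE 0.71) below it. Without that restriction, all 12 of the largest differences rested on fewer than 6 spots on an array. A single spot underlay 3 of these 12, and 4 included a spot at the top value of its array.

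Both particle comparisons use the same saline array. Their lists shared 13 accessions above saline, where independent lists of these sizes would share 0.544, and 151 below saline, where independent lists would share 51.1. Across accessions, which are not independent replicates, the 2 sets of differences correlated with r = 0.94 (Spearman's coefficient 0.89). Simulated unchanged arrays with only spot noise gave r = 0.98. The noise of the shared saline array enters both differences, and it was the largest of the 3 in the simulation. The 90th percentile of the spot SD was 0.89 on saline, 0.41 on silica and 0.49 on TiO2. Sharing alone does not set this value. The observed covariance was 2.16 and the simulated covariance was 0.163. Over the 565 accessions with every spot measured on all 3 arrays, the covariance was 0.694 against a simulated 0.0267, r was 0.88 against 0.93, and the lists shared 12 accessions above saline and 73 below it. The simulation leaves out variation between arrays, the single saline array cannot be split, and part or all of the excess may come from that array. Without the differences, the centred ratios of silica and TiO2 correlated with r = 0.78 across the 662 accessions (Spearman 0.78), those of silica and saline with r = 0.47 (Spearman 0.49) and those of TiO2 and saline with r = 0.55 (Spearman 0.64).

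**Figure D1:**
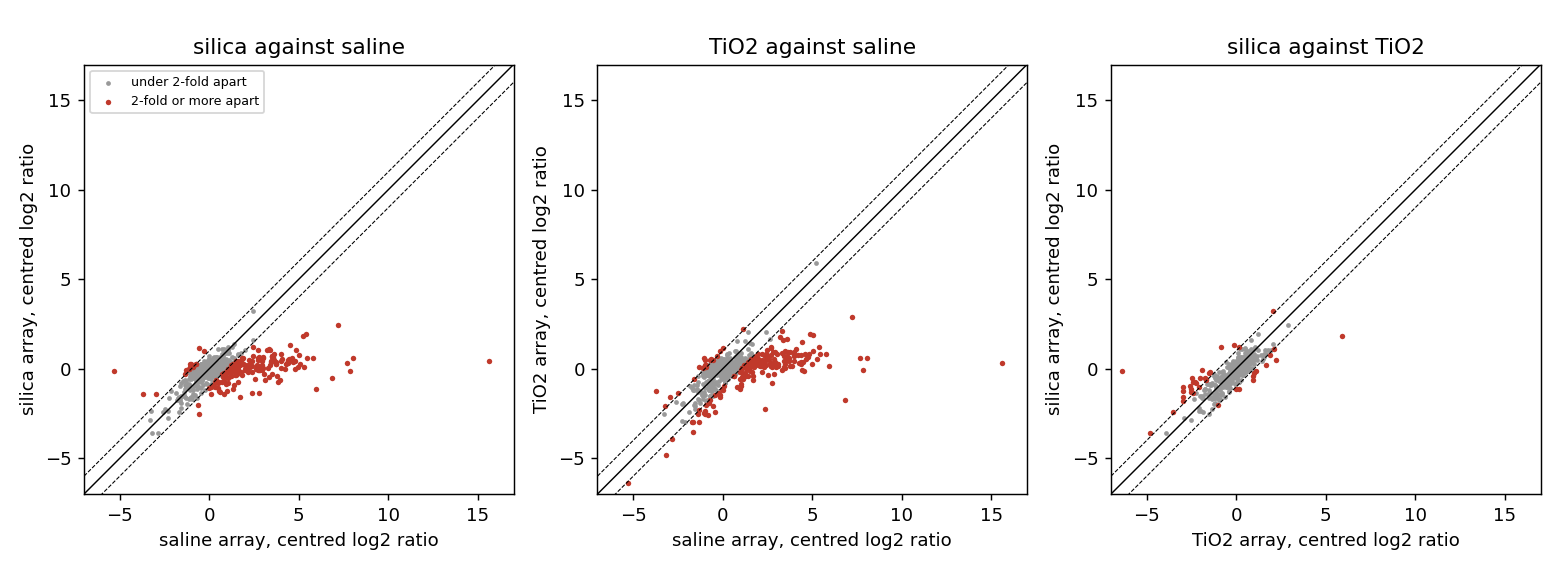
Centred log2 ratios of the 662 accessions with a value on all 3 arrays, 1 point per accession, with 1 array on each axis. The solid line marks equal ratios and the dashed lines a 2-fold difference, and red points are at least 2-fold apart: 201 for silica against saline, 205 for TiO2 against saline and 39 for silica against TiO2.

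The third comparison sets silica against TiO2 and uses the saline array only in the choice of accessions. *Alox5* was the 1 named gene of 11 that was 2-fold apart: its centred ratio was -1.15 ± 0.093 (SD, n = 6 spots) on the silica array and -2.51 on the TiO2 array, a difference of 1.36 (SE 0.042), or 2.56-fold. This difference was 0.86 after removal of the trend with the ratio, 1.01 under quantile normalization and 2.13 on one scale, which widens both arrays. *Mbnl2* differed by 0.25 (SE 0.034), but by -0.16 under quantile normalization and -0.22 after trend removal. *S1pr1* differed by -0.18 (range over the alternatives -0.30 to -0.12), *Rab4a* by 0.13 (0.12 to 0.27) and *Prkag2* by 0.12 (0.10 to 0.18). *Cdkn1b* differed by -0.0080 (SE 0.019), *Rbpj* by -0.0097 (SE 0.025) and *Arhgap35* by -0.094 (SE 0.11), each less than its SE over spots and with a sign that turned under other scalings or centrings. *Vezf1* differed by 0.056 (0.043 to 0.18), *Col16a1* by -0.089 (-0.16 to -0.032) and *F8a* by -0.089 (-0.14 to -0.032).

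**Figure D2:**
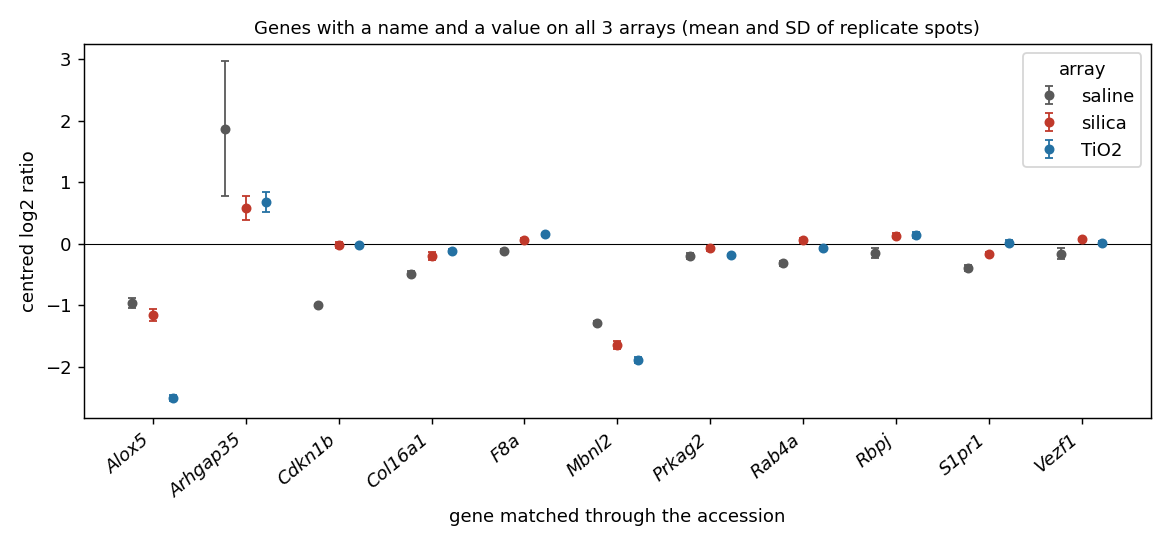
Centred log2 ratio on each array of the 11 genes with a name and a value on all 3 arrays; points are means and bars SDs over the measured replicate spots of 1 array. *Alox5* lies at -2.51 on the TiO2 array against -1.15 on silica, *Cdkn1b* lies at -0.99 on saline against -0.018 on silica, and *Arhgap35* on saline has an SD of 1.10.

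Of the 662 accessions, 39 (5.89%) were at least 2-fold apart between silica and TiO2, 27 with the silica ratio above and 12 with the TiO2 ratio above. Of 653 accessions with every spot measured on both arrays, 35 were 2-fold apart, and the spots of 34 of these did not overlap, against 343 (52.5%) of all 653. Among accessions with every spot also measured on the saline array, the largest differences were AI849947 (2.07, SE 0.20) and AI850037 (1.94, SE 0.019) with silica above, and AI843783 (-1.22, SE 0.070) and AI840698 (-1.22, SE 0.21) with TiO2 above. Without that restriction, 2 of the 12 largest differences rested on fewer than 6 spots on an array, 1 of them on a single spot. The split turned when accessions blank on the saline array were let in. Over the 834 accessions measured on both particle arrays, 128 were 2-fold apart, 38 with silica above and 90 with TiO2 above. The 172 accessions blank on saline held 89 of these, and TiO2 was above in 80 of the 89. With the arrays on one scale the split over the 662 accessions was 46 with silica above and 56 with TiO2 above, under quantile normalization it was 36 and 44, and after trend removal 20 and 19.

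Some matched genes had no value on the saline array, and their deposited log2 ratios are given without centring. *Epha5*, an ephrin receptor gene, had 3.10 ± 2.51 (SD, n = 5 spots) on silica and 4.0 ± 1.76 (SD, n = 2 spots) on TiO2, closer together than either SD. *Ifrd2* had 5.07 ± 2.81 (SD, n = 5 spots) on silica and was blank on TiO2. *Hspb3* and *Ralgps1* were blank on all 3 arrays.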

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

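Alternatives restricted to accessions with every spot measured, without top-value spots or without the saline array were chosen after seeing the data. Silica against saline gave 201 accessions 2-fold apart, and 342 at 1.5-fold, 123 at 3-fold, 90 after removal of the trend with the ratio and 118 of 565 with every spot measured on all 3 arrays, centred anew on those 565 (113 with the centring on 662). TiO2 against saline gave 205, and 353 at 1.5-fold, 108 at 3-fold, 123 under quantile normalization, 86 after trend removal and 133 with every spot measured, again centred anew (120 with the centring on 662). Silica against TiO2 gave 39, and 106 at 1.5-fold, 10 at 3-fold, 80 under quantile normalization, 102 with the arrays on one scale, and 128 over the 834 accessions measured on both arrays, which is also the count without the saline array. For this comparison these last 2 settings are the same calculation. Its values enter the totals below (34, 305 and 37) under both. The other 19 of 34 alternative counts stayed within 1.5 times the main count. Some of these could hardly move. Limiting the saline comparisons to the 2 arrays compared changed nothing, since every accession measured on saline was measured on both others. Leaving out top-value spots touched few spots. A higher threshold lowers the counts and a lower one raises them by construction. With every spot measured the share also fell, to 20.9% (from 30.4%) for silica against saline. For TiO2 against saline it fell to 23.5% (from 31.0%), so fewer accessions alone do not explain these falls. The common scale widened the silica and TiO2 arrays, which raises the count between them by construction. For the other settings the cause was not tested. For the 11 named genes, 67 of 305 alternative values were identical to the main value, most of them under settings that could not move these genes, and 111 of the other 238 moved by less than the SD over spots. Some of the 111 could hardly move either. Leaving out top-value spots shifted every named gene of a saline comparison by the same small amount. Centring anew on accessions with every spot measured did the same for silica minus TiO2. The 111 are therefore no measure of stability. The sign turned in 37 of the 305, of which 32 were for differences under 2-fold in the main setting (*Col16a1*, *S1pr1*, *Mbnl2*, *Prkag2* and others, given with their comparisons). The other 5 turned a difference of at least 2-fold, all for *Arhgap35*: silica minus saline was 0.54 under quantile normalization and 0.61 after trend removal, and TiO2 minus saline was 0.44, 0.54 and, on one scale, 0.060. Its saline value rests on 5 spots with an SD of 1.10, and the cause was not tested. No paired analysis was possible because each group has 1 array, and no array could be left out of a group.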

Other observations

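All tests in this part except that on the scale of the saline array were chosen after the result was seen.

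Blanks of the particle arrays lay within those of the saline array. All 88 accessions blank on the silica array and all 133 blank on the TiO2 array were also blank on the saline array, where independent blanks would share 28.3 and 42.7. Accessions blank on saline had high ratios elsewhere: their median deposited ratio was 0.83 on silica and 1.72 on TiO2, against 0.064 and 0.010 for accessions with every saline spot measured. The 53 accessions measured on silica and blank on TiO2 had a median silica ratio of 1.92, and the 8 measured on TiO2 and blank on silica a median TiO2 ratio of 2.94.

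The saline array stood apart from both particle arrays, with 30.4% of accessions 2-fold away from silica. Few measured spots do not account for it alone, since 20.0% of the 565 accessions with every spot measured were still 2-fold apart (113 accessions, with the centring on all 662). Those 565 still hold top-value spots. With top-value spots left out, 200 of 661 accessions (30.3%) were 2-fold apart, so those spots do not account for it alone either. A wider scale of that array stays open. On one scale, silica against saline gave 180 accessions and silica against TiO2 102, a ratio of 1.76. Its bootstrap interval over accessions, 1.48 to 2.14, spans the 1.5 set beforehand (the interval was added after the counts were seen). The ratio cannot decide the question, because the common scale widens the silica and TiO2 arrays at the same 2-fold threshold. That raises the silica against TiO2 count, which was 39 without it. A weak signal in the denominator channel of the saline array also stays open: saline minus silica correlated with the TiO2 ratio across accessions (Spearman 0.28), as it predicts, but a wider scale predicts this too. An effect of both particles cannot be told apart from these, since there is 1 array per group.

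Silica and TiO2 differed in opposite directions in different accessions. Where saline was blank, the TiO2 ratio was above the silica ratio in 81.4% of 172 accessions; spot noise does not account for this, since among all 97 that were fully measured the spots lay apart with TiO2 above in 48 and with silica above in 3. A weaker denominator channel on the TiO2 array is a candidate explanation, which these values allow and do not separate from an effect of the particle or of the dose. The 27 accessions with silica 2-fold above TiO2, among them that of *Alox5*, had low ratios: their median silica ratio was -0.67 (upper quartile -0.11). A weak denominator on the silica array would give high ratios. However, the 27 come only from accessions measured on saline, and accessions blank on saline, which had higher ratios, were left out. Their low ratios therefore do not decide about such a denominator. After trend removal 17 of the 27 stayed 2-fold apart and 26 stayed above 0. Their median difference moved from 1.36 to 1.18, with single values from -0.24 to 5.16 after removal. The lowess fit gives less weight to accessions far from it, so this move cannot show how much a trend accounts for. Such a trend stays open for the set and for single accessions, beside the particle, the dose and the single array. A wider TiO2 array would place TiO2 above silica at high ratios and below it at low ratios, as in both sets. The SD of the centred ratios was 0.87 on TiO2 and 0.68 on silica, but the median absolute deviations were close (0.25 and 0.24). The trend was removed only over accessions measured on saline. Whether a wider TiO2 array accounts for both sets was therefore not tested and stays open.

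The highest values repeat exactly. The 10 values above 10 were identical within each array: 15.896 at 6 spots on saline, 15.996 at 3 spots on silica and 15.827 at 1 spot on TiO2. They lie 0.104, 0.0040 and 0.173 below the log2 of the largest 16-bit number, which is consistent with a ratio set to that maximum and then multiplied by one constant per array. The single TiO2 spot cannot show a repeat, and whether the same constant was applied to the other spots was not tested.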
